A study of Mus musculus with 125 samples.

How the data were processed

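Single cholinergic interneurons of the dorsal striatum were collected by patch-seq, in which the contents of 1 recorded cell are drawn into the patch pipette and sequenced. The cells came from mice in which ChAT-Cre drives the red fluorescent reporter tdTomato, and each was assigned by its recording to an active, a silent or an unknown state of spontaneous firing. The mice were either wild-type (WT) or heterozygous for Df(16)1 (Het), a deletion on chromosome 16 that models the human 22q11 deletion. Cells came from 10 mice, 5 of each genotype, aged 82 to 95 days. Collection batch 1 held 3 WT and 3 Het mice of both sexes with 73 cells, and batch 2 held 2 WT and 2 Het mice, all male, with 52 cells. Both WT mice of batch 2 shared 1 birth date and both Het mice another, so genotype and birth date coincide there.

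Libraries were made with a SMART-Seq kit (the LP version for mRNA of single cells), per the labels. M stands for 1e6 counts. Trim Galore 0.6.3, STAR 2.7.9a and RSEM 1.3.3 are named with the builds GRCm38 and mm10, per the submitters' processing notes. The authors deposited 1 table of expected counts per gene and cell, as estimated by RSEM, not normalized and already in whole numbers. It held 55545 entries, of which 92 were spike-in transcripts. The spike-ins were left out of totals and tests and made up a median of 0.000204% of the counts of a cell. Reads that fit several near-identical genes are shared among them by an estimate, so counts of paralogs and pseudogenes are uncertain. Whether the counting used strand is not given in the sources used here, and 14 of the 19 measured genes of the deletion interval overlap another annotated gene. Coordinates and identifiers are those of the GENCODE M21 annotation of GRCm38. It held exactly 1 gene of the same symbol for 39444 of the 40143 genes with a read (98.3%).

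The total per cell ranged from 11.59 to 77.1 M counts, with a median of 37.96 M, and 5985 to 22673 genes were detected. The kit does not count molecules, so counting intervals and the floor of 3 counts cover counting error only. No pair of cells had identical values and the highest correlation between any 2 cells was 0.946.

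The mouse was the replicate. Counts were summed over the cells of a mouse, or over its cells of 1 state, and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) after TMM scaling and edgeR's expression filter, with Benjamini-Hochberg adjustment at 0.05. The genotype test used 10 sums with batch as a covariate. The state test and the genotype by state interaction used active and silent sums of mice with at least 3 cells in both states, with the mouse as a block, which left the 6 mice of batch 1. The pairing comes from the animals themselves, since both states were recorded in the same mouse on the same day. Genotype was also tested in active cells alone, with batch as a covariate and 9 mice, and in silent cells alone, with the 6 mice of batch 1. Standard errors of log2 fold changes were derived from the fold change and the quasi-likelihood F. Levels are counts per M (CPM) of the summed cells, as mean ± SD over mice.

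Lists of genes were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1). Each of the 5 comparisons covered 20 lists. They were the deletion interval, its border genes, cholinergic identity, ion channels of pacemaking and repolarisation, activity-regulated genes, neuromodulator receptors, glutamate and GABA receptors, synaptic vesicle release, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, microRNA processing, heat shock and integrated stress response, and markers of spiny projection neurons, other striatal interneurons, cortical glutamatergic neurons, astrocytes, oligodendrocytes and precursors, microglia, and endothelial, mural and blood cells. A few genes belong to more than 1 list, such as Dgcr8 in the deletion interval and microRNA processing. Single values per mouse were compared with exact permutation tests, 2-sided, or with exact sign flips within mice (scipy 1.17.1).

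Lists, tests, covariates and most alternatives were fixed before the data were examined. Named genes followed a rule fixed at the same time. It took the members of the deletion interval and border, the genes of smallest p in each direction (10 where they pass, otherwise 5, given as values that did not pass), up to 4 members of each list that pass adjusted over the list alone or otherwise up to 2 of smallest p, Chat, Slc5a7 and Slc18a3, and the sex-linked genes. Gene models with a Gm number or a Rik name were outside that rule. Of the genes the rule took, the text gives a selection with values, and some are not reported here.

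The alternatives were DESeq2's size factors and DESeq2's Wald test (DESeq2 1.42.0), no expression filter, cells with at least 3000 genes, limma on the mean over cells of log2(CPM + 1), leaving out each mouse, each batch alone, no batch term, sex or the share of silent cells as a covariate, leaving out the cells of each of the 3 electrophysiologists or of unknown state, other minimum numbers of cells, no block and single cells as units. A further 5 alternatives were added after seeing the data. They covered cells in which Chat, Slc5a7 and Slc18a3 sum to at least 100 CPM (115 cells), genes with a read in at least 50% of the cells, both together, the genotype by batch interaction, and the share of silent cells among the 115 cells.

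The tests were checked on simulated counts drawn from the means and library sizes of the real sums, with 200 genes changed. The changed genes were drawn only from genes at a mean of at least 4 log2 CPM. The shares recovered therefore do not cover genes at lower levels. At a log2 change of 3, edgeR recovered 94% of the changed genes for genotype (21965 genes), 97% for state (18915), 40% for the interaction (22333), 80% in active cells (19667) and 89% in silent cells (20204). At a log2 change of 1 the shares were 24%, 21%, 0%, 4% and 4%. Other splits of the mice were refitted, 100 of 126 possible splits for genotype and for genotype in active cells, all 32 for state and all 10 for the interaction and for silent cells. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.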

Results

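The transcriptomes of 125 cells were compared, 62 from WT and 63 from Het mice. Among the Het cells 35 were active, 24 silent and 4 of unknown state, and among the WT cells 27, 28 and 7. Median depth was 37.11 M counts in active cells of either genotype, 43.02 M in Het silent cells and 37.06 M in WT silent cells. Total counts per cell averaged 39.1 ± 4.96 M over Het mice and 37 ± 4.96 M over WT mice (SD, n = 5 each). A single ribosomal RNA-like gene, CT010467.1, took 0.231% to 50.3% of the counts of a cell, with a median of 4.42%. The sums tested held 302.73 to 561.3 M counts per mouse.

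The deletion was seen first. The Df(16)1 animals carry 1 copy of a segment of chromosome 16, and the listed genes of that segment span positions 17900709 to 18835261 of GRCm38. Of 19 measured interval genes 17 were lower in Het mice, with a median log2 fold change of -1.08. Adjusted over the list alone, 12 fell. Ranbp1, a regulator of the Ran cycle of nuclear transport (chromosome 16, 18239784 to 18248732), was at 90.1 ± 13.1 CPM in Het and 164 ± 23.1 CPM in WT mice (SD, n = 5 each), a log2 fold change of -0.87 (SE 0.13).

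Also among the members that fell were the septin gene Sept5 (-1.17), Ufd1 of protein degradation (-1.08), Tango2 (-0.97), the platelet glycoprotein gene Gp1bb (-1.85), the tRNA methyltransferase gene Trmt2a (-1.19), Ess2 (-0.75), the palmitoyltransferase gene Zdhhc8 (-1.35), Dgcr6 (-0.80), the thioredoxin reductase gene Txnrd2 (-1.11) and Arvcf (-1.48). Slc25a1, the mitochondrial citrate carrier, had -0.71 (SE 0.35) and did not pass, and neither did Dgcr8 (0.06, SE 0.40), which acts in microRNA processing, or Prodh (0.36, SE 2.58). Several of these genes overlap each other on the chromosome, such as Ranbp1 with Trmt2a and Sept5 with Gp1bb, so reads may be divided between them. The list gave a camera p of 3.8e-22, and 1.5e-05 with an estimated correlation (adjusted p 0.000306).

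The mean over the interval genes was 3.38 ± 0.36 log2 CPM in Het and 4.51 ± 0.23 in WT mice (SD, n = 5 each), and the ranges did not overlap. The difference of -1.13 had an exact permutation p of 0.00794, the smallest that 5 against 5 mice can give, and 0.0167 with labels permuted within batches. It was -1.24 within batch 1 (exact permutation p = 0.1, the smallest possible for 3 against 3) and -0.96 within batch 2 (exact permutation p = 0.333). The 15 measured genes at the border of the segment had a median of -0.05 and 0 passed adjusted over the list alone. Dgcr2 (-0.08), Mrpl40 (0.12) and Hira (-0.62) lie at its ends. The border mean differed by 0.12 log2 CPM (exact permutation p = 0.611), with 0.53 in batch 1 and -0.50 in batch 2.

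**Figure D1:**
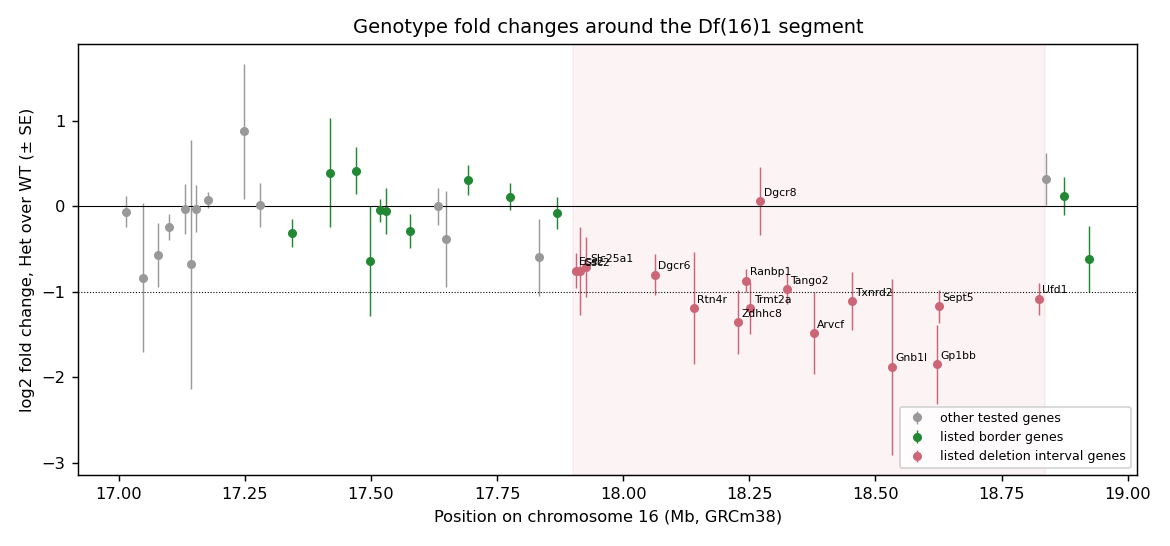
Log2 fold changes (Het over WT, ± SE) of tested genes with a mean above 1 log2 CPM along chromosome 16, with the span of the listed interval genes shaded. Sept5 (-1.17) and Ranbp1 (-0.87) lie near the dotted line of 1 lost copy, and Dgcr2 (-0.08) and Mrpl40 (0.12) at the borders lie near 0.

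**Figure D2:**
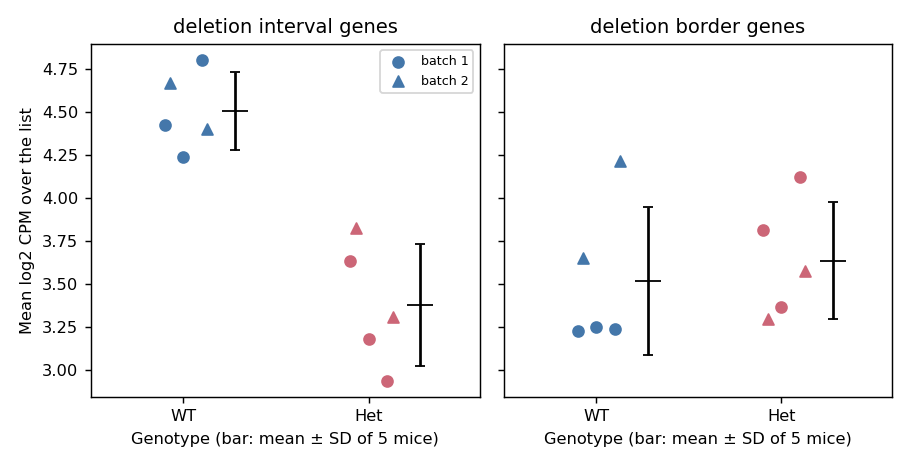
Mean log2 CPM of the interval genes and of the border genes in each mouse by genotype, with circles for batch 1, triangles for batch 2 and bars for mean ± SD of 5 mice. All 5 Het mice lie below all 5 WT mice for the interval genes (3.38 against 4.51).

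Outside the interval, no gene separated the genotypes after adjustment. Across 21965 genes tested in 10 mice, edgeR called 0 genes at an adjusted p under 0.05, with 733 at an unadjusted p under 0.05 where chance gives about 1098. DESeq2's Wald test called 101 (33 higher and 68 lower in Het), and limma on cell means called 0. Without the WT mouse GDH687 edgeR called 1 gene. The genes of smallest p outside the interval did not pass. They were Kdm6a, an X-linked histone demethylase (-1.05, SE 0.20), the kinase gene Braf (-0.54, SE 0.11), Tmem223 (-0.59), Hps4 (-1.21) and Zbtb21 (-0.87) on the lower side, and Pds5b of the cohesin complex (0.68, SE 0.15), the cytochrome heme lyase gene Hccs (0.51), Mrpl44 (0.80), Agtr1b (6.85) and Cdc23 (0.49) on the higher side. Agtr1b was read in 31 of 125 cells.

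The transcripts that mark a cholinergic neuron did not pass. Chat, which makes acetylcholine (chromosome 14, 32408203 to 32465989), was at 433 ± 62.5 CPM in Het and 262 ± 191 CPM in WT mice (SD, n = 5 each; log2 fold change 1.13, SE 0.70). The WT spread came from batch 2, with Chat at 110 CPM in GDH687 and 15.0 CPM in GDH693, and Chat had 0.55 (SE 0.38) without GDH693 and -0.01 (SE 0.15) in batch 1 only. The choline transporter gene Slc5a7 had 0.30 (SE 0.32) and Slc18a3, the vesicular acetylcholine transporter gene that lies within Chat, 0.17. Of 20 measured identity genes 17 were positive, and 0 passed adjusted over the list alone (camera adjusted p 0.0446; p = 0.373 with an estimated correlation). A total of 10 cells had almost no Chat, Slc5a7 or Slc18a3, 8 of them in the WT mouse GDH693.

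Other lists held no member that passed adjusted over the list alone. Microglia markers were negative in 12 of 12 (camera adjusted p 4.7e-05; p = 0.172 with an estimated correlation), with Aif1 at -1.13 (-0.60 without GDH693). Mitochondrially encoded genes were negative in 13 of 13 (camera adjusted p 0.00137; p = 0.273 with an estimated correlation), with mt-Co3 at -0.40 and mt-Nd4 at -0.33. Cytosolic ribosomal protein genes were negative in 67 of 86 (camera adjusted p 0.0473; p = 0.609 with an estimated correlation). Camera did not pass for the remaining lists. Negative members were 51 of 80 ion channel genes, 25 of 34 activity-regulated genes, 17 of 37 neuromodulator receptors, 19 of 39 glutamate and GABA receptors, 14 of 38 vesicle release genes, 24 of 77 nuclear-encoded oxidative phosphorylation genes, 8 of 15 microRNA processing genes and 13 of 30 stress genes. Among markers of other cells they were 15 of 18 for spiny projection neurons, 10 of 11 for other interneurons, 2 of 5 for cortical neurons, 10 of 12 for astrocytes, 7 of 13 for oligodendrocytes and precursors, and 6 of 8 for endothelial, mural and blood cells. The spiny projection neuron share of counts was 0.9185% in the WT mouse GDH693 and 0.0549 to 0.0663% in the other WT mice. In Het mice it was 0.0555 to 0.149%, so the lower values in Het mice for these markers may rest on GDH693. The oligodendrocyte share of counts was 0.0650 ± 0.0295% in Het and 0.202 ± 0.163% in WT mice (SD, n = 5 each; exact permutation p = 0.0714, adjusted 0.608), and the microglia share 0.0687 ± 0.0481% against 0.161 ± 0.143% (exact permutation p = 0.159). The WT mouse GDH693 raised both WT means, with an oligodendrocyte share of 0.459% against 0.0308 to 0.244% and a microglia share of 0.412% against 0.0499 to 0.124% in the other WT mice, and in batch 1 the microglia share was 0.0828 to 0.116% in Het and 0.106 to 0.124% in WT mice, while the oligodendrocyte share was 0.0464 to 0.0717% against 0.119 to 0.244%.

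Of 20 comparisons of depth, detected genes, mitochondrial share and marker shares, 0 had an adjusted exact p under 0.05, but with so few mice a single measure could not have passed. Detected genes averaged 15466 ± 1379 in Het and 15041 ± 1791 in WT mice (SD, n = 5 each; exact permutation p = 0.706). The transcripts of Xist and of the Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty followed the sex given for each mouse, apart from Xist in GDH699. In that male Xist averaged 3.68 CPM, against 0.0072 to 0.0877 CPM in the other males and 30.5 to 88.6 CPM in the females.

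How often cells were silent was asked next. The share of silent cells among cells of known state was 41.5 ± 30.7% in Het and 53.5 ± 23.5% in WT mice (SD, n = 5 each), a difference of -12.0 percentage points (exact permutation p = 0.516). Within batch 1 the difference was 8.14 points (exact permutation p = 0.3), with 63.5 ± 8.53% in Het and 55.4 ± 5.81% in WT mice (n = 3 each). Within batch 2 it was -42.2 points (exact permutation p = 0.333, the smallest possible for 2 against 2). The direction thus differed between batches, and leaving out 1 mouse at a time gave -20.8 to -3.39 points. Among cells with cholinergic transcripts, a choice added after seeing the data, the share was 43.1 ± 32.6% in Het and 46.1 ± 16.6% in WT mice (n = 5 each). How cells were chosen for recording is not given in the labels, so these are shares of collected cells.

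Active and silent cells of the same mouse differed in 2 myelin genes. Mobp, a structural protein gene of myelin (chromosome 9, 120149707 to 120181484), was at 83.3 ± 39.3 CPM in active and 459 ± 379 CPM in silent cells (SD, n = 6 mice), a log2 fold change of -2.13 (SE 0.24). Mbp, the myelin basic protein gene (chromosome 18, 82475146 to 82585637), was at 226 ± 75.9 against 995 ± 769 CPM (-1.86, SE 0.36). Both were lower in active cells in 6 of 6 mice and fell when adjusted over the list alone, the only 2 of 9 measured oligodendrocyte markers to do so, while 8 of 9 were negative. The list gave a camera adjusted p of 0.00294, and p = 0.0109 with an estimated correlation (adjusted p 0.218). The oligodendrocyte share of counts moved alike, at 0.0421 ± 0.0137% in active and 0.177 ± 0.143% in silent cells (n = 6; exact sign-flip p = 0.0312, the smallest possible; adjusted 0.312).

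The size of the myelin difference depended on the cells taken. Without the cells of electrophysiologist E3, which left fewer mice, Mobp was at -0.85 (SE 0.82) and Mbp at -0.38 (SE 0.82), and with all mice that had both states Mobp was at -1.13 (SE 1.06) and Mbp at -1.17 (SE 0.73).

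**Figure D3:**
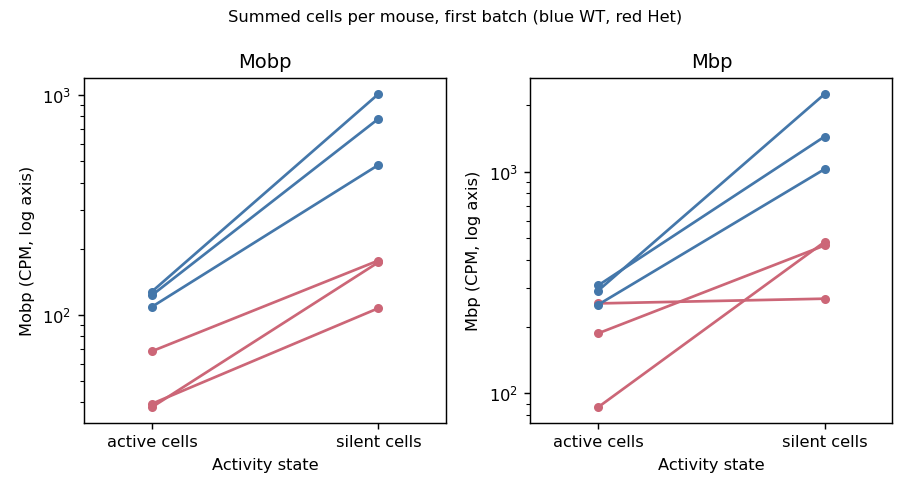
CPM of Mobp and Mbp (log axes) in the summed active and silent cells of each of 6 mice of batch 1, lines joining the states of 1 mouse, blue for WT and red for Het. Mobp rises from a mean of 83.3 in active to 459 CPM in silent cells.

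No gene separated the states after adjustment over all genes. Across 18915 genes in 6 mice, edgeR called 0 genes, with 549 at an unadjusted p under 0.05. DESeq2's Wald test called 410 (85 higher and 325 lower in active cells), and limma on cell means called 0. Values of smallest p, none of which passed, were Tnik, a kinase of the postsynapse (0.89, SE 0.18), the synaptic adhesion gene Nlgn1 (0.69, SE 0.18), Capza1 (0.60), Serpina9 (6.22, read in 27 of 73 cells) and Ntng2 (6.42, read in 13) on the higher side, and Papss2 (-6.37, read in 13), the interferon-induced Ifit3 (-10.9, read in 15) and Plekhb1 (-1.93) on the lower side. Ion channels of pacemaking had 33 positive and 45 negative members (camera adjusted p 0.907), and activity-regulated genes 15 and 18 (camera adjusted p 0.810). In these lists 0 genes passed adjusted over the list alone. Trpc4 had 0.45 (SE 0.16), the potassium channel gene Kcnd1 1.17 (SE 0.54) and Jun -1.56 (SE 0.93). Chat (-0.04, SE 0.16), Slc5a7 (-0.01, SE 0.08) and Slc18a3 (-0.25, SE 0.40) were at similar levels in both states.

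Whether the difference between states itself differed by genotype was tested as an interaction in the same 6 mice. A positive value means that active minus silent was larger in Het than in WT mice. Of 12 measured microglia markers 12 were positive and 2 rose adjusted over the list alone, Aif1 (2.15, SE 0.37) and Tyrobp (1.91, SE 0.38), which encode proteins of microglia and macrophages (camera adjusted p 1.6e-05; p = 0.095 with an estimated correlation). Aif1 was at 32.9 ± 10.3 CPM in WT active and 71.7 ± 8.53 CPM in WT silent cells, and at 59.1 ± 32.6 CPM in Het active and 27.8 ± 7.35 CPM in Het silent cells (n = 3 each). When every cell weighed the same, Tyrobp had -0.44, and with all mice that had both states Aif1 had 1.11 (SE 2.16).

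Camera also passed for spiny projection neuron markers (14 of 18 positive, adjusted p 0.000156; p = 0.136 with an estimated correlation), mitochondrially encoded genes (13 of 13 positive, adjusted p 0.00022; p = 0.280), activity-regulated genes (27 of 35 positive, adjusted p 0.00317; p = 0.104) and nuclear-encoded oxidative phosphorylation genes (65 of 77 negative, adjusted p 0.0348; p = 0.504), each losing its call with the estimated correlation. Members with values that did not pass were mt-Nd6 (0.99, SE 0.39), Nr4a2 (8.28, SE 2.62) and Sdhd (-0.80, SE 0.23). Across 22333 genes edgeR called 0, with 985 at an unadjusted p under 0.05, DESeq2's Wald test called 779 (388 positive and 391 negative) and limma on cell means called 0. The smallest p belonged to Cd86 (13.6, read in 19 of 73 cells), Sat1 (1.63, SE 0.23), Dlx2 (10.7, read in 20), Cd300a (9.73) and the synaptic scaffold gene Nbea (1.39, SE 0.23) on the positive side and to the RNA-binding protein gene Ralyl (-1.44, SE 0.21), Acp1 (-1.21), Tmem183a (-1.33), Shoc2 (-2.33) and Hist2h2be (-14.8, read in 16) on the negative side, as values that did not pass. The sizes for Cd86 and Dlx2 rest on a WT active group near 0 (mean 0.00423 CPM each), and that for Hist2h2be on groups near 0 as well (0.00300 CPM in Het active and 0.00818 CPM in WT silent cells).

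In active cells alone, part of the deletion interval was lower in Het mice and a few markers of spiny projection neurons, the main output neurons of the striatum, were higher. Of 18 measured interval genes 7 fell adjusted over the list alone, with a median of -1.08 (p = 0.000536 with an estimated correlation, adjusted 0.0107). All 18 of 18 spiny projection neuron markers were positive and 3 rose adjusted over the list alone. Among these were the adenylyl cyclase gene Adcy5 (77.1 ± 34.4 CPM in 5 Het against 29.6 ± 9.17 CPM in 4 WT mice, 1.34, SE 0.36) and Ppp1r1b, which encodes DARPP-32 (2.21, SE 0.65). The list gave a camera adjusted p of 4.2e-06, and p = 0.097 with an estimated correlation. When every cell weighed the same, Adcy5 had 0.31 and Ppp1r1b 1.17. The cell with the most counts gave 29.0% of those of Ppp1r1b and 20.4% of those of Adcy5. The active sum of the Het mouse GDH566 held 3 cells, and 1 of them lacked cholinergic transcripts and had Ppp1r1b at 1836 CPM. These differences therefore cannot be assigned to cholinergic neurons alone.

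The potassium channel gene Kcnc4 fell adjusted over the ion channel list alone (32 of 78 measured members were negative). It was read in 6 of 61 cells, with 3 counts in Het and 1816 in WT mice, a ratio of 808 with an exact 95% counting interval from 276 to 3921. Across 19667 genes in 9 mice edgeR called 0, with 731 at an unadjusted p under 0.05, DESeq2's Wald test called 280 (118 higher and 162 lower) and limma on cell means called 0. Among cells with cholinergic transcripts and genes read in at least 50% of them, edgeR called 1, Upb1, with 8.95 (edgeR adjusted p 0.0432). Over all active cells Upb1 had 8.52, at 6.98 ± 9.92 CPM in Het and 0.0215 ± 0.0138 CPM in WT mice, with 21 WT counts. It was read in 30 of 61 cells, and 38.7% of its counts came from 1 cell. The smallest p among genes that did not pass belonged to Stac3 (0 counts in Het, at least 169-fold lower against a floor of 3 counts over the group), Tmie, Odaph (-4.61) and Cyp2d26 (-8.14) on the lower side and to Rasl11b (2.30), the lysosomal gene Cd68 (3.61), the kinase gene Camkk2 (1.19, SE 0.25) and Camkv (2.18) on the higher side. Tmie had 2 counts in Het, a ratio of 797 with an exact counting interval from 220 to 6592. Stac3 was read in 6 of 61 cells and Tmie in 11, and these bounds do not cover which cells were collected. Chat had 0.36 (SE 0.51).

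In silent cells alone, several mitochondrial and deletion genes and a few myelin genes were lower in Het mice. Of 13 mitochondrially encoded genes 13 were negative and 11 fell adjusted over the list alone, among them the complex I gene mt-Nd5 (-0.54, SE 0.11), mt-Co1 (-0.45, SE 0.13), mt-Atp8 (-0.72, SE 0.21) and mt-Cytb (-0.66, SE 0.20). The list gave a camera adjusted p of 2.7e-07, and p = 0.159 with an estimated correlation. Mitochondrial counts made up 30.6, 15.6 and 13.2% of 3 WT silent cells, the first without cholinergic transcripts, and when every cell weighed the same mt-Co1 had -0.21 and mt-Cytb -0.35. Nuclear-encoded oxidative phosphorylation genes were positive in 65 of 77, with 0 passing adjusted over the list alone (camera adjusted p 0.00617; p = 0.349 with an estimated correlation). Of 19 measured interval genes 8 fell, with a median of -0.96 (p = 0.00222 with an estimated correlation, adjusted 0.0443).

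Some oligodendrocyte and microglia markers were lower in the silent cells of Het mice too. Of 11 oligodendrocyte markers 10 were negative and 3 fell adjusted over the list alone, among them Mobp (150 ± 41.6 CPM in Het against 768 ± 260 CPM in WT mice, n = 3 each; -2.35, SE 0.33) and Mbp (399 ± 124 against 1590 ± 614 CPM). Single WT cells held much of the Mbp, with up to 9662 CPM, while Mbp had -2.34 when every cell weighed the same and -1.87 in cholinergic cells only. The list gave a camera adjusted p of 0.00508, and p = 0.0378 with an estimated correlation (adjusted 0.378). Of 12 microglia markers 10 were negative and Aif1 fell (-1.38, SE 0.24; camera adjusted p 9.4e-05; p = 0.206 with an estimated correlation). Camera also passed for spiny projection neuron markers (14 of 18 negative, adjusted p 0.00934; p = 0.262 with an estimated correlation) and astrocyte markers (11 of 12 negative, adjusted p 0.0329; p = 0.181). Across 20204 genes in 6 mice edgeR called 0, with 967 at an unadjusted p under 0.05, DESeq2's Wald test called 243 (111 higher and 132 lower) and limma on cell means called 0. The smallest p among genes that did not pass belonged to Pcdhga8, a clustered protocadherin that shares exons with its neighbours (0 counts in Het, at least 4035-fold lower against a floor of 3 counts), Ism1 (0 counts in Het, at least 66.7-fold lower), Art3 and Syt17 on the lower side and to Cep72 (7.11), Armcx4 (1.94, SE 0.29), Them4 (1.72, SE 0.26), Zfp184 and AC110206.1 on the higher side. Of these Pcdhga8 was read in 7 of 43 cells, Ism1 in 6 and Zfp184 in 7, so the bounds cover counting error only and not which cells were collected.

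**Figure D4:**
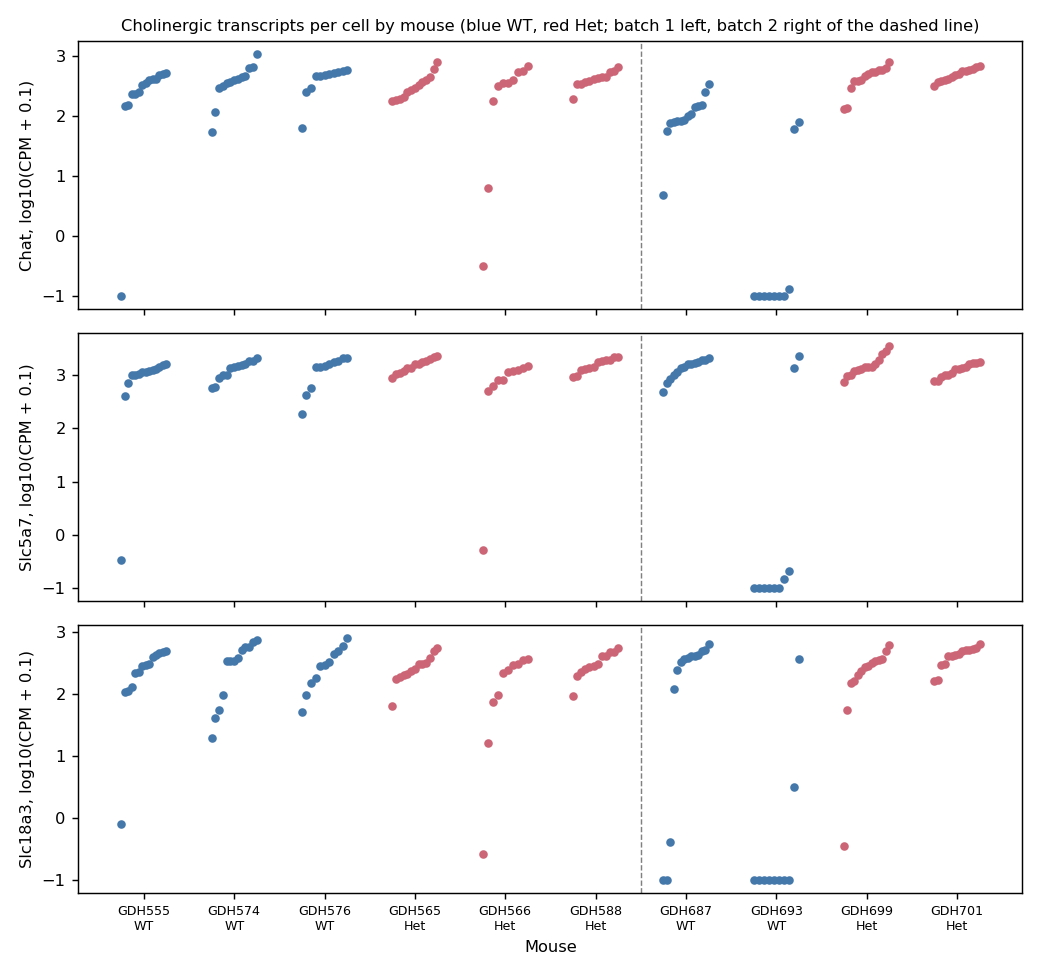
Chat, Slc5a7 and Slc18a3 in each of 125 cells by mouse, as log10 of CPM with 0.1 added, blue for WT and red for Het, batch 1 left of the dashed line. Of 10 cells of GDH693 8 lie at the bottom for all 3 genes, and Chat is lower in the remaining WT cells of batch 2 than elsewhere.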

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

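The marker shares of the cells without cholinergic transcripts, the genotype by batch test, the Chat comparisons within batch 2 and the Rpl15 read shares were chosen after the result was seen, and the tests of the other oligodendrocyte markers and of library complexity after Mobp but before their own values were seen.

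In 10 of 125 cells Chat, Slc5a7 and Slc18a3 summed to at most 0.954 CPM, while the lowest sum among the other 115 was 435 CPM. Of these cells 8 came from GDH693 and 1 each from GDH555 and GDH566. A median of 12047 genes was detected in them against 16132 in the others, and median depth was 25.8 against 38.4 M counts. One of them had 5985 genes, the lowest of all 125. Under the rule used, written after the result was seen, the drop in genes was too small to count as failed libraries. A part played by poorer libraries is not excluded. Transcripts of another striatal cell type in the pipette would fit. In 10 of 10 at least 1 marker share of another type lay above the 95th percentile of the cholinergic cells. The median spiny projection neuron share was 0.558% against 0.0412%. Several shares were checked, and how often the cholinergic cells passed at least 1 was not counted. The test cannot tell added RNA from a collected cell of another type, since both would raise such a share. Added RNA alone would not remove Chat, Slc5a7 and Slc18a3. No biological explanation was tested.

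GDH693 lay far from the other WT mice for detected genes (12025 against 15157 to 16432), spiny projection neuron share (0.9185% against 0.0549 to 0.0663%), astrocyte share (0.0982%) and microglia share (0.4122%). Other single mice far from their group were GDH555 for the cortical neuron share (0.0042%), GDH699 for the endothelial, mural and blood share (0.0384%), GDH566 for Ess2 (35.0 CPM), GDH687 for Txnrd2 (23.5 CPM) and GDH701 for Kcnc4 in active cells (0.00642 CPM against 0). Of 68 groups of mice tested 10 held such a mouse, most of them listed here, where chance gives about 1 in 20. The groups were quality values, marker shares, interval and identity values, and genes called within their lists.

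Chat was low in the WT mice of batch 2 alone, at 111 CPM in GDH687 and 74.9 CPM in the 2 cholinergic cells of GDH693, against 329 to 438 CPM in batch 1. Cells that are not cholinergic are an unlikely cause, since the log2 ratio of Het over WT in batch 2 was 2.44 among cholinergic cells only, and a lower yield of cholinergic transcripts in general is unlikely too, since Slc5a7 and Slc18a3 reached at most 0.40. The Het mice of batch 2 had 481 and 525 CPM, so processing of the second batch alone does not give low Chat. A strain variant on chromosome 14 that differs between the families could not be told from the test used. The test took the share of Rpl15-family reads given to 2 pseudogenes on chromosomes 15 and 9. The variant called for shares above all of batch 1 in both WT mice of batch 2 and below all of it in both Het mice. Both Het mice lay below in either set of cells, at 0.0624 and 0.0671%, where the lowest share in batch 1 was 9.00%. Among WT mice the share was 9.73% in the 2 cholinergic cells of GDH693 and 13.4% in GDH687, against at most 12.5% in batch 1. Over all cells these WT mice had 15.6 and 13.4%, so the sets of cells disagreed for the WT part. Birth date coincides with genotype in batch 2, and its effect was not tested.

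The difference between Het and WT mice differed between batches in the genotype by batch test for Gm10020 (-8.39, edgeR adjusted p 0.00115) and Rpl15-ps2 (-7.22, edgeR adjusted p 0.0135) over all cells, and for Gm10020 (-8.17) and Gm3591 (-7.76, edgeR adjusted p 0.00725) in cholinergic cells. Gm10020 and Rpl15-ps2 are annotated as processed pseudogenes and the split of reads between them and Rpl15 is uncertain, while the cause for Gm3591, annotated as protein-coding on chromosome 14, was not tested. In cholinergic cells Gm3373 (-4.64, edgeR adjusted p 0.0558), Gm3411 (-5.49, edgeR adjusted p 0.0636) and Chat (2.45, SE 0.27, edgeR adjusted p 0.0671), all on chromosome 14, did not pass. The share given to Gm10020 and Rpl15-ps2 was 0.0624 and 0.0671% in the Het mice of batch 2 and 9.21 to 15.6% in all other mice.

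Oligodendrocyte transcripts were higher in silent than in active cells of all 6 mice. RNA of oligodendrocytes in the pipette would fit, since the 5 other mature markers had a median of -1.21, though none of them passed singly. Lower complexity of silent libraries is an unlikely cause, since silent cells had fewer detected genes in only 2 of 6 mice. A change of myelin genes within the neurons themselves was not tested. Without the cells of electrophysiologist E3, who recorded in batch 1 only, Mobp was at -0.85 in the 3 mice left, so the recording may matter as well.

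The spike-ins, which no comparison used, had a median of 79 counts per cell (25 to 485).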

How the results depend on the processing

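Of 145 recomputed main results 134 were counted as the same. For gene counts this meant 0 genes again, and for the share of silent cells the same direction without passing. For the interval median it meant a shift smaller than the SD of the interval mean over Het mice. Whether single interval genes passed did not enter this count. DESeq2's Wald test called 101 genes for genotype, 410 for state, 779 for the interaction, 280 in active and 243 in silent cells, where edgeR called 0 each; the cause was not tested. Leaving out 1 mouse at a time gave 0 to 1 genes for genotype, and 0 in the other comparisons. Single cells as units gave 1 gene for state, CT010467.1. Without a replicate block, that is with active and silent sums not paired by mouse, the state test gave 0 genes, with 575 at an unadjusted p under 0.05 against 549. Cholinergic cells only with genes read in at least 50% of the cells, added after seeing the data, gave 1 gene in active cells. The interval median stayed between -1.12 and -0.84, while the genes that fell adjusted over the list alone went from 12 of 19 to 0 with batch 2 only and to 5 of 17 without E1, with fewer mice or cells. The share of silent cells turned to 8.14 points with batch 1 only. Camera with an estimated correlation passed 3 list tests of 100 and fry 3, against 20. Of 6024 recomputed values of named genes, 5283 stayed within 1 SE, 639 moved further, 101 passed after adjustment and 1 that had passed over its list reversed, the interaction of Tyrobp (-0.44 with limma on cell means); 261 had the other sign. Mobp between states was -1.09 with limma on cell means, -1.13 with at least 1 cell per sum and -0.68 with single cells as units. The minimum of 3000 genes removed no cell. Depth per sum was 89.041 to 361.35 M for state. At a log2 change of 1 the simulated test recovered 21% of changed genes there and 0% for the interaction, with genes at low levels left out.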

Other observations

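The refits on other splits of the mice were planned, and the cause given for the largest split was looked for after the result was seen. For genotype 56 of 100 splits called as many genes at an unadjusted p under 0.05 (733 for the real labels, 1936 for the highest other), and for state 21 of 32 (549 and 983), so chance cannot be excluded for these counts. In active cells 59 of 100 splits did (731 and 4640). With the batch term, the split with 4640 genes set GDH566 against the other mice of batch 1, so its count rests on 1 small sum. The active sum of GDH566 held 3 cells, 1 of them without cholinergic transcripts. The same sum is part of the genotype test in active cells. These counts of splits include the real labels. For the interaction only the real labels, 1 of 10 splits, reached that count (985, and 979 for the highest other) and in silent cells 3 of 10 (967 and 1311), and 10 splits are too few to exclude chance.

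In a window from 16983382 to 19244834 on chromosome 16 65 genes were tested, 42 of them outside the span of the interval genes with a median of -0.04 and 0 at an unadjusted p under 0.05. The silent share was 50, 61.5, 54.5, 18.2 and 83.3% in the WT mice and 53.8, 70, 66.7, 10 and 7.1% in the Het mice. Batch 1 had a median of 16545 detected genes per cell and batch 2 14376. One cell of the male mouse GDH699 had Xist at 51 CPM.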
